A study of Mus musculus with 6 samples.

How the data were processed

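RNA was measured in primary mouse bone marrow-derived macrophages (BMMs) from control mice (Ctrl) and from mice lacking the mitotic checkpoint kinase Bub1 in myeloid cells (Bub1 cKO). Per the labels' protocols, the cells were kept for 3 days in M-CSF at 20 ng/ml, a growth factor for macrophages, and then for 2 days in M-CSF at 20 ng/ml with RANKL at 50 ng/ml, the cytokine that turns macrophage precursors into osteoclasts. Libraries were made from 25 ng of total RNA with a QuantSeq 3' kit, per the labels' protocols, so that reads come from near the 3' end of each transcript. The labels list 3 libraries per genotype, 6 in all, with nothing that says whether these came from separate animals or cultures. The p-values therefore measure the spread between these libraries, which may be technical.

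All values come from 1 table, the authors' own comparison of Bub1 cKO against Ctrl for 15982 genes, which gives 1 value per gene and group. Values per library were not used here. The file header names RaNA-seq, a web service for RNA-seq analysis. The aligner or quantifier, the genome build, the annotation and the test are not given in the sources used here. The deposited expression columns name no unit and were read as TPM, because the Ctrl values sum to 999891, the Bub1 cKO values to 999954 and the mean column to 999923. CPM columns would sum alike, so CPM cannot be excluded, and TPM below stands for the expression value as deposited. In TPM proper a gene's reads are divided by transcript length, which lowers long transcripts in a 3' tag library but leaves the ratio between groups of a gene with 1 transcript as it is. The deposited log2 change equals log2 of (Bub1 cKO + 1)/(Ctrl + 1) within 0.002 in 15982 genes, so it understates the change of genes with low values. The deposited test statistic and its standard error were read as scores of the authors' test. The deposited p-value equals the 2-sided normal tail of the statistic in 15974 genes, with a tolerance of 0.0006 on both, and in 8 genes the authors' table sets it to 1 whatever the statistic.

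The standard error belongs to the log2 change that the test itself estimated, which is the statistic times the standard error, and not to the deposited log2 change. Of 7159 genes with a mean of at least 5 TPM, 1033 differ between these changes by more than 1 standard error. Over the whole table the signs are opposite in 1519 genes, 10 of which have an unadjusted p under 0.05. Whether the group values and the test rest on the same quantification is not given in the sources used here. Below, "log2 change" means the deposited one and "the test's own log2 change" the other. The direction of a gene is that of the statistic, and no SD, n or interval from single libraries can be given. The depth of the libraries is unknown, and the authors' standard error stands for the precision. Its median is 0.186 on the log2 scale for genes of at least 100 TPM, 0.346 for the 4101 genes between 10 and 100 TPM and 3.43 for genes under 1 TPM.

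The design fixed before the data were examined assumed values per library, with a model fitted to each gene. With a comparison table this was replaced by the authors' adjusted p under 0.05, with no threshold on the fold. Gene lists were fixed before the data were examined, 30 in all, and tested with cameraPR of limma 3.58.1 (R 4.3.3) on the deposited statistic. This test asks whether the statistics of a list lie higher or lower than those of the other genes. It used genes with a mean of at least 1 TPM (10881), the entry with the highest mean for each symbol (10874 symbols), a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 3 such members. An estimated correlation and the rotation test fry need values per library and could not be run. For each list, calls were also counted with p adjusted over the list alone. On simulated statistics for this comparison and 10874 genes, a list with its 44 statistics shifted by 0.8 was called in 94% of 100 runs, and unshifted lists in 0.222%, when genes of a list shared a correlation of 0.01. With a shared correlation of 0.05 these shares were 85% and 4.28%. The Benjamini-Hochberg step, run on 15982 simulated genes of which 200 were shifted by 5, called 96.0% of those, with 2.54% of calls false. These simulated statistics were independent, so this checks the step itself and does not measure the power of the calls below.

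Named genes follow a rule fixed before the data were examined: Bub1, then the 10 largest rises and 10 largest falls by log2 change among genes past the threshold with a mean above the median of 3.67 TPM, leaving out unnamed gene models, then up to 4 members per list with the smallest p. The part of the rule that asked for groups without overlap needs values per library and was not applied. Only 9 falls passed, and the place left was filled by the smallest p. Other genes are said to be chosen after their values were seen. Gene positions and types come from GENCODE M21 (GRCm38), which holds 14622 of the 15982 identifiers with their version and 15910 without it. The build is that of this annotation, since the table gives no positions. The table holds 14230 protein-coding genes and 1664 pseudogenes, and the pseudogenes carry 16.5% of the Ctrl and 16.9% of the Bub1 cKO TPM. Where a gene has near-identical copies, reads may have been split between them. Alternatives covered the filter on low values, the pseudocount, the rule for a call, the adjustment, overlapping genes and pseudogenes, and the settings of the list test. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.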

Results

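The data hold 1 contrast: BMMs from Bub1 cKO mice against BMMs from Ctrl mice, both on day 2 of osteoclast induction with RANKL, with 3 libraries per genotype. The series title names osteoclast activation, NF-κB and inflammatory arthritis as the subjects of the study. Each gene has 1 TPM value per genotype in the authors' deposited table, with a log2 change, a standard error and p-values.

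The targeted gene was examined first. Bub1 (ENSMUSG00000027379.13, chromosome 2, 127801122 to 127831865 on the minus strand, GRCm38), a kinase of the spindle checkpoint, stood at 6.73 TPM in Ctrl and 5.32 TPM in Bub1 cKO in the authors' deposited table. Its log2 change was -0.29, with a standard error of 0.42 and an adjusted p of 0.985 in the authors' deposited table. The 95% interval of the test's own log2 change ran from -1.15 to 0.50. No fall was detected, a fall within this interval could have been missed, and a fall beyond -1.15 lies outside it. The deleted exons are not given in the sources used here, and 3' tags outside the deleted part would still be counted, so this value does not check the labels.

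Few single genes differed between the genotypes. At an adjusted p under 0.05 the authors' deposited table holds 29 genes, 18 higher and 11 lower in Bub1 cKO. At an adjusted p under 0.1 it holds 44, with 25 higher and 19 lower. At an unadjusted p under 0.05 there were 769 genes, where chance alone would give 799, and under 0.01 there were 223, where chance would give 160. Among genes with a mean of at least 1 TPM these counts were 682 against 544 and 205 against 109. Of the 29 genes, 2 are pseudogenes (Gm47626 and Gm48082), 3 overlap another gene of the table on the same strand (Pagr1a, Gm42742 and Scamp4), and 3 belong to the lists of erythroid or neutrophil markers (Hbb-bs, Hbb-bt and Cxcr2). Gm47626, Gm48082, Gm42742 and Scamp4 fall outside the rule for named genes and were chosen after their values were seen.

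Among the rises that the rule for named genes takes, hemoglobin genes had the largest log2 changes: in the authors' deposited table the beta-globin gene Hbb-bt went from 1.01 to 31.8 TPM and Hbb-bs from 5.44 to 77.3 TPM, with log2 changes of 4.03 and 3.60. The authors' deposited table also has Pmepa1, a membrane protein that restrains TGF-β signalling, at 1.77 TPM in Ctrl and 17.6 TPM in Bub1 cKO, a log2 change of 2.75. Cxcr2, a chemokine receptor of neutrophils, rose from 2.59 to 10.9 TPM in the authors' deposited table (log2 change 1.73). Recomputed with a pseudocount of 5 in place of 1, the log2 changes of Hbb-bt, Pmepa1 and Cxcr2 were 2.61, 1.74 and 1.07. Itgav, the alpha-V integrin with which osteoclasts attach to bone, rose from 183 to 394 TPM, with a log2 change of 1.10, a standard error of 0.25 and an adjusted p of 0.013 in the authors' deposited table. Tfrc, the transferrin receptor for iron uptake, rose from 25.7 to 56.5 TPM, a log2 change of 1.11 with a standard error of 0.21 in the authors' deposited table. The tubulin gene Tubb6 rose from 48.5 to 111 TPM in the authors' deposited table (log2 change 1.19, standard error 0.24). Smaller rises in the authors' deposited table were those of the transporter Slc16a6 (log2 change 1.04), the histone methyltransferase Dot1l (0.78) and the phospholipid enzyme Lpcat1 (0.69).

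Among the falls, Lyz2, the lysozyme gene of macrophages (chromosome 10, 117277331 to 117282321 on the minus strand), dropped from 2141 to 762 TPM in the authors' deposited table, with a log2 change of -1.49, a standard error of 0.28 and an adjusted p of 0.00033. The authors' deposited table shows Sat1, an enzyme of polyamine breakdown, falling from 153 to 70.1 TPM (log2 change -1.11, standard error 0.20). Abcg1, a cholesterol exporter, fell from 7.76 to 1.83 TPM (log2 change -1.63, or -0.90 with a pseudocount of 5), and Vcan, the proteoglycan versican, from 36.7 to 12.3 TPM in the authors' deposited table. Cd72, a lectin-like receptor, fell from 42.7 to 15.9 TPM in the authors' deposited table (adjusted p = 0.049), a call lost when p was adjusted again without pseudogenes and overlapping genes. Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, fell by 0.41 on the log2 scale from 5153 TPM, and Olfr620 and Bmt2 fell by 0.64 and 0.55 in the authors' deposited table. Nfam1, the filled place, did not pass (adjusted p = 0.055, log2 change -0.42) in the authors' deposited table, but did when p was adjusted again over genes of at least 1 TPM or over those above the median mean. Its test's own log2 change was -0.61.

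The largest fall, Pagr1a, has a mirror image in the authors' deposited table: Pagr1a went from 24.1 to 0.468 TPM while Gm42742, on the same strand, went from 0.612 to 26.1 TPM. Pagr1a spans 127015033 to 127017352 on chromosome 7 and Gm42742 spans 127015051 to 127021097, an overlap of 2302 bases (GRCm38). The test's own log2 change of Pagr1a was -7.78, against -4.10 in the log2 column of the authors' deposited table and -2.41 with a pseudocount of 5.

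**Figure D1:**
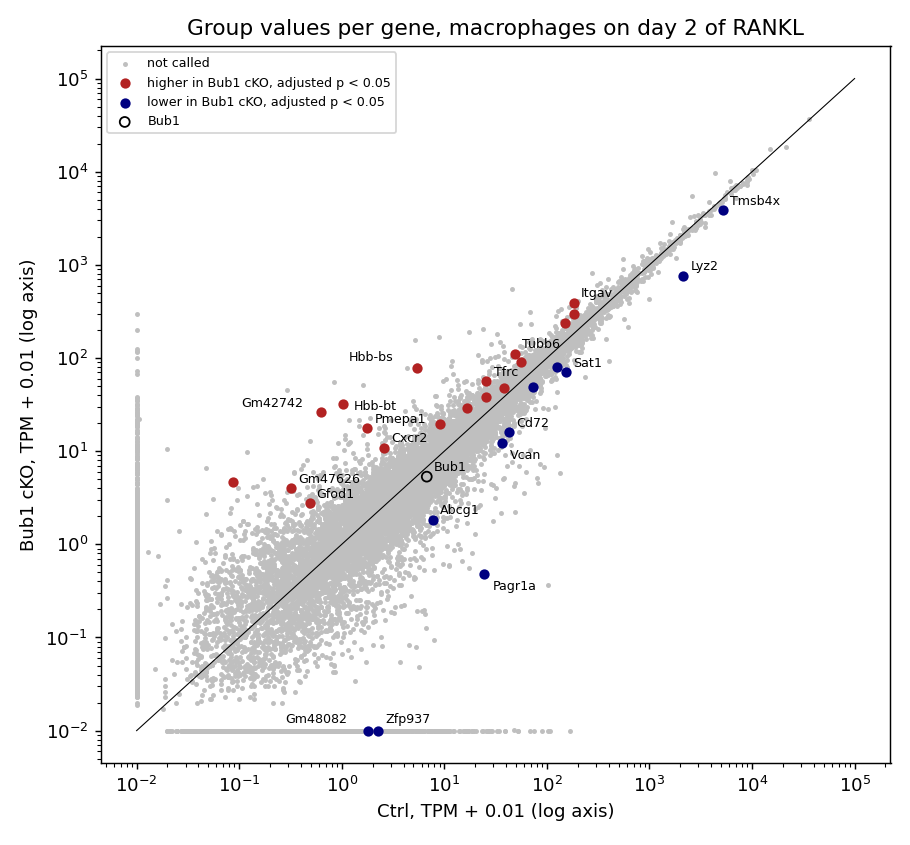
TPM of each gene in Bub1 cKO (vertical axis) against Ctrl (horizontal axis), both as TPM + 0.01 on log axes, 1 point per gene. Coloured points are the 29 genes with an adjusted p under 0.05, 18 higher (red) and 11 lower (blue) in Bub1 cKO, the open circle is Bub1 at 6.73 and 5.32 TPM, and the line marks equal values.

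**Figure D2:**
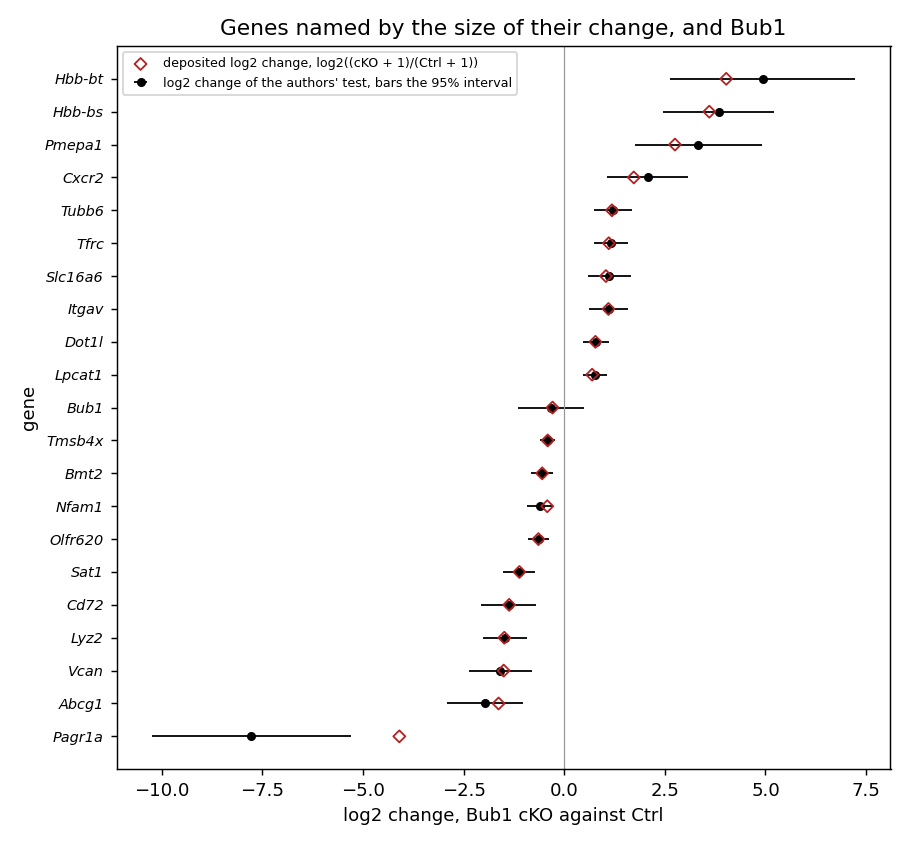
Log2 change of Bub1 cKO against Ctrl (horizontal axis) for Bub1 and the 20 genes named by size (vertical axis). Black points are the test's own log2 change with bars for the 95% interval, red diamonds the deposited log2 change. The bar of Bub1 covers 0, and for Pagr1a the changes differ, at -7.78 and -4.10.

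The next question was whether genes of osteoclast formation differed. As a group they were higher in Bub1 cKO: 32 of 44 tested members had a positive statistic, the median log2 change was 0.34, and the list passed the set test (cameraPR, adjusted p = 5.37e-08). Over all genes 2 members passed, Itgav and Jdp2, and adjusted over the list alone 5 did, with Nfatc1, Ocstamp and Myo1d besides. In the authors' deposited table Jdp2, a transcription factor needed for osteoclast formation, rose from 149 to 239 TPM (log2 change 0.68, standard error 0.15). Nfatc1, the master transcription factor of osteoclasts, stood at 48.7 and 73.3 TPM and the fusion gene Ocstamp at 11.1 and 22.1 TPM, with adjusted p of 0.094 and 0.373 over all genes in the authors' deposited table. Among effector genes, the authors' deposited table has Ctsk, the collagen-degrading protease of osteoclasts, at 537 and 696 TPM and the phosphatase Acp5 at 531 and 639 TPM. Mmp9 was at 688 and 657 TPM, and the RANKL receptor gene Tnfrsf11a at 50.4 and 56.4 TPM with a statistic of the opposite sign (-0.19) in the authors' deposited table. Acp5, Mmp9 and Tnfrsf11a were chosen after their values were seen. At an unadjusted p under 0.05, 14 members were higher and 1, Csf1r, was lower. The member Anpep, chosen after its values were seen, fell from 102 to 28.4 TPM, but its statistic was only -0.10 in the authors' deposited table. The call does not hold when the log2 change takes the place of the statistic (adjusted p = 0.608). Beside these genes the globin and neutrophil transcripts described below were also higher in Bub1 cKO.

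The 14 tested fusion genes did not pass as a group (cameraPR, adjusted p = 0.763). Adjusted over the list alone, Ocstamp and Cd44 were higher and Sirpa and Cd47, which bind each other across cells, were lower. Sirpa was at 122 TPM in Ctrl and 81.3 TPM in Bub1 cKO in the authors' deposited table (adjusted p = 0.067 over all genes). Sirpa starts at 129592835 on chromosome 2, which also carries Bub1 (127801122 to 127831865). Whether variants linked to the targeted locus play a part was not tested. Of 21 negative regulators of osteoclast formation 14 had a negative statistic, and the list did not pass (cameraPR, adjusted p = 0.143). Adjusted over the list alone, 2 of them were lower, Sirpa and Cyld.

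NF-κB target genes were not separated from other genes by the set test. Of 38 tested members 19 had a positive and 19 a negative statistic, and the list did not pass (cameraPR, adjusted p = 0.832). The median log2 change was -0.02 and the mean statistic -0.07, while the median statistic was 0.03, so the signs differ. No member passed the authors' adjusted p over all genes or over the list alone, and at an unadjusted p under 0.05 there were 3 higher and 3 lower. The smallest p belonged to Icam1, an adhesion molecule at 15.1 TPM in Ctrl and 8.49 TPM in Bub1 cKO, and Slfn2 at 58.1 and 38.7 TPM in the authors' deposited table. Plau and Ccl2 went the other way, with 7.39 against 13.8 TPM and 15.1 against 31.0 TPM in the authors' deposited table. Nfkbia, the inhibitor that NF-κB induces, was chosen after its values were seen and stood at 433 and 435 TPM in the authors' deposited table. Of 39 components of the NF-κB pathway, 16 had a positive and 23 a negative statistic, and the list did not pass (cameraPR, adjusted p = 0.460). Cyld, a deubiquitinase that restrains NF-κB and RANK signalling, was its one member to pass over the list alone, at 18.8 TPM in Ctrl and 10.2 TPM in Bub1 cKO in the authors' deposited table (adjusted p = 0.277 over all genes). Inflammatory cytokines and chemokines did not pass (14 of 22 positive, cameraPR, adjusted p = 0.250). Interferon-stimulated genes did not pass either, with 27 of 39 statistics negative (cameraPR, adjusted p = 0.0849).

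Genes of mitosis were lower in Bub1 cKO. Of 75 tested genes of G2/M and mitosis 56 had a negative statistic, the median log2 change was -0.24, and the list passed (cameraPR, adjusted p = 8.32e-06). The unadjusted p of this list reaches 0.05 at a shared correlation between its genes of 0.134, which could not be estimated here. Globin and neutrophil transcripts were higher in the same comparison. No single member passed the authors' adjusted p over all genes or over the list alone, and at an unadjusted p under 0.05 there were 8 lower and 0 higher. The authors' deposited table gives Cdc25b, a phosphatase that starts mitosis, a log2 change of -1.04, and the kinesin Kif23 at 120 TPM in Ctrl and 72.0 TPM in Bub1 cKO. Cdc25b starts at 131186949 on chromosome 2, the chromosome of Bub1, and variants linked to the targeted locus were not tested. The call does not hold with the log2 change as the statistic (adjusted p = 0.465). Of 20 spindle checkpoint genes, 5 of them also in the mitosis list, 16 had a negative statistic, and the list missed the threshold (cameraPR, adjusted p = 0.050002). It passed with ranks in place of the statistic (adjusted p = 0.0244) and with no filter on low values (adjusted p = 0.0317), and in 0 of the other 5 settings. Mad2l1 was chosen after its values were seen: it went from 45.4 to 7.59 TPM in the authors' deposited table, a log2 change of -2.43, while the test's own log2 change was -0.54 and the adjusted p 0.985. S-phase genes did not pass, with 25 positive and 30 negative statistics (cameraPR, adjusted p = 0.749). Replication-dependent histone genes (cameraPR, adjusted p = 0.763) and p53 target genes (cameraPR, adjusted p = 0.206) did not pass. Some histone genes were measured with large errors, so their list says little about replication. Hist1h4h was at 0 and 10.85 TPM and Hist1h2ai at 15.9 and 0 TPM in the authors' deposited table, with standard errors of 2.185 and 2.532. For p53 targets the median statistic was 0.37 and the median log2 change -0.00.

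Macrophage genes were lower in Bub1 cKO, with 16 of 24 statistics negative and a median log2 change of -0.28 (cameraPR, adjusted p = 0.00193). The erythroid and neutrophil lists were higher in the same comparison (adjusted p = 6.09e-09 and 9.25e-05), so the fall was not seen apart from them. Lyz2 passed over all genes, and Lyz2 and Gpnmb over the list alone. Gpnmb was at 443 and 361 TPM, Csf1r, the M-CSF receptor gene, at 116 and 96.7 TPM, and Apoe, the apolipoprotein E gene with a positive statistic, at 35.7 and 62.6 TPM in the authors' deposited table. Without Lyz2 the list still passed (adjusted p = 0.0354), and with the log2 change as the statistic it did not (adjusted p = 0.794).

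Genes of the unfolded protein response were higher, with 19 of 26 statistics positive and a median log2 change of 0.16 (cameraPR, adjusted p = 0.00903), beside the rise of the erythroid and neutrophil lists. The endoplasmic reticulum chaperone gene Calr, at 552 and 693 TPM in the authors' deposited table, passed over the list alone. With a preset correlation of 0.05 this list no longer passed (adjusted p = 0.0947), nor with the log2 change as the statistic (adjusted p = 0.947). Its unadjusted cameraPR p reaches 0.05 at a shared correlation of 0.084. The median statistic of the list, 0.35 beside a mean of 0.71, was above that of 90.48% of 10000 random lists of like size and level. MHC class II genes, with 6 of 7 statistics positive, passed narrowly (cameraPR, adjusted p = 0.0493) and did so in 1 of 7 other settings, with adjusted p from 0.0272 to 0.608. H2-DMb2, at 0.243 and 2.41 TPM, reached the mean of 1 TPM through Bub1 cKO. Without it the list did not pass (cameraPR, adjusted p = 0.142). Ciita, at 1.30 and 0.345 TPM with a statistic of -1.95, stayed below that mean and was not tested.

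The remaining lists did not pass. Adjusted p by cameraPR was 0.666 for lysosome and V-ATPase genes, 0.135 for oxidative phosphorylation genes, 0.579 for glycolysis genes and 0.909 for cholesterol synthesis genes, whose mean and median statistics differ in sign (0.04 and -0.16). It was 0.135 for heat-shock and immediate-early genes and 0.143 for mitochondrial-genome transcripts. The set test looks for a shift in a common direction, and members of the lysosome and V-ATPase list moved both ways. At an unadjusted p under 0.05, 8 of its 53 tested genes were higher and 6 lower, beside 682 of all 10881 genes of at least 1 TPM. Adjusted over the list alone, the lysosomal genes Ctsc and Lipa were lower. Ctsc went from 29.1 to 15.2 TPM and Lipa from 255 to 182 TPM in the authors' deposited table, and mt-Nd2, the mitochondrial transcript that passed over its list alone, from 3842 to 4751 TPM.

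**Figure D3:**
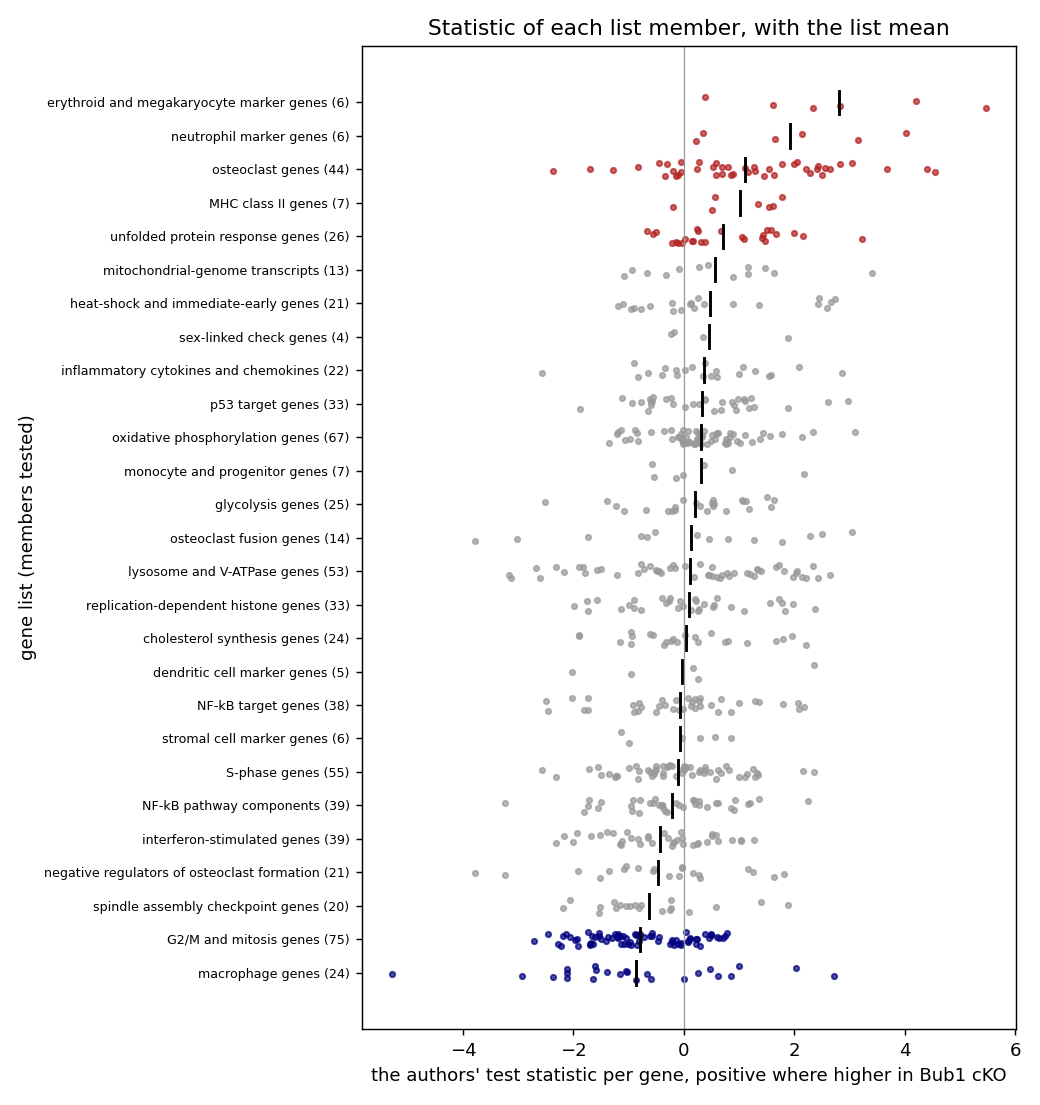
The authors' test statistic of each tested gene (horizontal axis, positive where higher in Bub1 cKO) for the 27 tested gene lists (vertical axis, with the number of members). Each point is 1 gene, black bars are list means, and lists past an adjusted p of 0.05 are red (5 higher) or blue (2 lower). Osteoclast genes lie to the right (32 of 44 positive) and genes of G2/M and mitosis to the left (56 of 75 negative).

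Markers of other cells that a bone marrow culture can hold differed as well. All 6 tested erythroid and megakaryocyte markers had a positive statistic (cameraPR, adjusted p = 6.09e-09), and all 4 globin genes passed over the list alone. Alas2, a member chosen after its values were seen, was at 0 TPM in Ctrl and 2.07 TPM in Bub1 cKO in the authors' deposited table. It reached the mean of 1 TPM only through Bub1 cKO, so its sign was fixed by the filter. The preset correlation of 0.01 also treats the 4 globin genes as nearly independent. The alpha-globin genes Hba-a1 and Hba-a2 were at 4.36 and 8.83 TPM in Ctrl and at 77.8 and 169 TPM in Bub1 cKO in the authors' deposited table. Because globin genes come in near-identical pairs, the split of reads within a pair is uncertain. The platelet and megakaryocyte gene Pf4, a member of this list chosen after its values were seen, had 266 and 288 TPM in the authors' deposited table. Of the 12 neutrophil markers present, 6 reached a mean of 1 TPM and were tested, and all 6 had a positive statistic (cameraPR, adjusted p = 9.25e-05), with Cxcr2 and S100a9 past the threshold over the list alone. S100a9 was at 38.0 and 115 TPM and S100a8 at 41.9 and 92.8 TPM in the authors' deposited table, both genes of the calprotectin complex. Ngp, chosen after its values were seen, was at 0.963 and 4.54 TPM in the authors' deposited table, and reached the mean of 1 TPM through Bub1 cKO. Ltf, the lactoferrin gene, chosen after its values were seen, went the other way in its values, at 12.3 and 6.74 TPM with a statistic of 0.22 in the authors' deposited table. With the log2 change as the statistic the neutrophil call was lost (adjusted p = 0.201). Monocyte and progenitor genes (cameraPR, adjusted p = 0.647), stromal markers (adjusted p = 0.909) and dendritic cell markers (adjusted p = 0.942) did not pass. Their mean and median statistics have opposite signs, at 0.30 and -0.01, -0.07 and 0.13, and -0.04 and 0.17. Of the B-cell markers 2 reached a mean of 1 TPM, and of the markers of T and NK cells and of mast cells and basophils 0 did, so these lists were not tested. The sex-linked check found Y-chromosome transcripts in both groups, with Ddx3y at 8.77 and 11.7 TPM and Eif2s3y at 19.0 and 15.7 TPM in the authors' deposited table (list adjusted p = 0.588). Xist, the list's marker of female cells, is not among the genes given. A mix of male and female libraries within a group could therefore not be seen.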

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

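Alternatives that concern the adjustment, overlapping genes, the minimum of 1 TPM for single genes, the correlation of 0.05, the log2 change as the statistic, the list member with the smallest p, protein-coding genes and the test's own log2 change were chosen after seeing the data. No paired analysis was possible because the table used gives 1 value per group. For the same reason leave-one-out fits, median-centring, quantile normalization, other tests per gene, the estimated correlation, fry and other splits of the libraries were not run. Recomputing the adjusted p gave 29 genes, all 29 shared with the deposited calls. Genes of at least 1 TPM gave 37 (28 shared), those above the median mean 35 (24 shared), and leaving out pseudogenes and overlapping genes 23. With a log2 change of at least 1 there were 20. The looser rule of an unadjusted p under 0.05 and a fold of at least 1.5 gave 511 genes, 252 higher and 259 lower, by its construction. Of the 7 lists called, 1 (erythroid markers) passed with the log2 change as the statistic, a measure that does not weigh genes by their error, and the osteoclast list then had an adjusted p of 0.608. In the other 6 settings the osteoclast list passed, with adjusted p from 7.65e-09 to 0.000647. NF-κB targets passed in 0 of 7 settings (adjusted p 0.217 to 0.996). With pseudocounts of 0.1 and 5 the log2 changes of 15 and 11 of 208 other genes moved by more than their standard error, and that of Bub1 did not. With the test's own log2 change in place of the deposited one, 39 of the 208 moved as far. Some genes that were not called changed sign, such as Itgax, from -1.24 to 2.31. No call of a list reversed its direction in any alternative run. Gene calls take their direction from the same statistic under every rule, and a pseudocount cannot change a sign. Only the test's own log2 change could differ in sign from the deposited one, and for the called genes it did not. The depth is unknown, so what it limits could not be measured.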

Other observations

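Tests on globin and neutrophil genes, on Lyz2 and on the summed values of Pagr1a and Gm42742 were chosen only after the result was seen, and the tests on ribosome biogenesis, proteasome and chaperonin genes and on overlapping pairs before it.

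Nucleolar genes stood among the smallest p-values, and from this came the hypothesis that ribosome biogenesis genes were higher in Bub1 cKO as a group. It was tested on the members of a new list that had not been noticed first. Of these 76 genes 57 had a positive statistic and the median log2 change was 0.27. Their cameraPR p was 7.69e-06, the direction that the hypothesis asks for (adjusted p = 0.0196 over 3 lists with a correlation of 0.05). With the log2 change as the statistic the list did not pass (adjusted p = 0.167), and globin and neutrophil genes were higher in the same comparison. Among the members noticed first, Ncl, the abundant nucleolar protein nucleolin, was at 671 and 821 TPM and Nop58 at 262 and 384 TPM in the authors' deposited table, with Gtpbp4 alone past the adjusted threshold at 184 and 294 TPM. The same test on 30 proteasome subunit genes, 23 of them positive, gave a p of 0.00443, but the adjusted p was 0.0582 with a correlation of 0.05 and 0.725 with the log2 change as the statistic. For 6 genes of the CCT chaperonin, 5 of them positive, the p was 0.102, which leaves open whether that group moved. In all 3 lists the members tested come from the same libraries as those noticed first and may move with them. These tests are therefore not independent of the search that prompted them.

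Other genes past the adjusted threshold, chosen after their values were seen, included Fosl2, a gene of the AP-1 family, at 25.3 and 37.9 TPM and the kinase gene Map4k4 at 38.5 and 47.3 TPM in the authors' deposited table. For Map4k4 the log2 change was 0.29 and the test's own log2 change 0.70. The calls on Zfp937 and Gm48082 rest on Ctrl values of 2.24 and 1.80 TPM against values listed at 0 or close to it in the authors' deposited table. Gm48789 and Anpep do not pass and were also chosen after their values were seen. Gm48789, a processed pseudogene, went from 4347 to 9766 TPM with an adjusted p of 0.055 in the authors' deposited table. Anpep, a member of the osteoclast list, went from 102 to 28.4 TPM, a log2 change of -1.81, while its statistic was -0.10 in the authors' deposited table.

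Globin genes and neutrophil genes were higher in Bub1 cKO. The 4 globin genes summed to 19.6 TPM in Ctrl and 356 TPM in Bub1 cKO. The beta-globin genes lie on chromosome 7 and the alpha-globin genes on chromosome 11. The alpha-globin rise argues against variants linked to a locus on chromosome 7 as the only source. Its mean test's own log2 change was 3.95, with a mean standard error of 1.53. Over all genes the adjusted p was 0.502 for Hba-a2 and 0.857 for Hba-a1 in the authors' deposited table. Olfr620, which fell, lies close to the beta-globin genes, at 103604895 to 103612534 on chromosome 7. A part of linked variants in the beta-globin rise therefore stays open. Red-cell RNA carried along with the macrophages stays open: the globin changes lie within 1.28 on the log2 scale, but the margin, 2 median standard errors of 1.34, is set by the genes' own large errors. Neutrophil RNA stays open as well, since the 6 of 6 positive neutrophil statistics are the observation itself and test no source of it. A rise in some libraries and not others stays open too: the globin standard errors were 1.12 to 3.39 times the median of genes with a like value in the lower group (median ratio 2.08), above 1.5 in 2 of the 4 genes.

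Pagr1a and Gm42742 changed in opposite directions. Their summed values were 24.7 TPM in Ctrl and 26.5 TPM in Bub1 cKO, a log2 change of 0.10. This restates the opposite changes for which the pair was picked, so a shift of shared reads between overlapping gene models stays open. Across 268 same-strand overlapping pairs Pearson's r of the statistics was -0.15 (permutation p = 0.012) and Spearman's rho -0.02 (permutation p = 0.70), over genes that are not independent replicates. Without Pagr1a and Gm42742 r was -0.02 (permutation p = 0.73). Without the 2 pairs whose first gene had the statistic farthest from the median, r was 0.01. The relation thus rests on Pagr1a and Gm42742, and whether such shifts are general stays open. Scamp4, also past the threshold, overlaps Adat3, with statistics of 4.0 and -2.11. Among pairs with both unadjusted p under 0.05, 2 moved in opposite directions and 2 in the same direction. A difference in the transcript made, or a strain variant that moves the assignment of reads, was not tested.

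Lyz2 fell more than other macrophage genes. The 23 others had a median test's own log2 change of -0.28 (range -1.05 to 0.77) and Lyz2 had -1.48. That is 4.29 of its standard errors below the median, beyond the 3.08 that allow for picking the most extreme of 24 genes. This bound was added after the first cut-off of 2. The distance argues against a fall of equal size in all members, though Mrc1 at -1.05 lies inside the Lyz2 interval. A group loss of uneven size stays open, because the bound uses the error of Lyz2 alone and other members differ as well, with Apoe at 0.77 (standard error 0.28). Mice with myeloid deletion often carry Cre recombinase inserted in Lyz2, which disrupts that allele, but the labels do not name the driver. If so, a change of -1 would follow from 1 lost allele, and the 95% interval of Lyz2, from -2.03 to -0.93, holds it. Such an allele is a candidate explanation for the fall, and whether the Ctrl mice carried it is not given in the sources used here.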
